A study of Mus musculus with 16 samples.

How the data were processed

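RNA was measured by sequencing in 16 libraries from the distal part of mouse forelimb buds. Per the labels, the forelimb tips of B6 embryos were treated with trypsin on ice, the ectoderm (the surface epithelium) was pulled off the mesoderm with forceps, and the polyadenylated RNA of each layer was sequenced with a stranded kit. The libraries form 8 groups of 2: ectoderm and mesoderm at 4 stages 1 day apart, the first E9.5 and the last E12.5. The ectoderm and the mesoderm library with the same stage and replicate number came from the same batch of embryos, so that each stage has 2 embryo batches. Per the labels, replicate 1 and replicate 2 libraries were extracted with different versions of the same RNA kit.

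Per the submitters' processing notes, the upstream tools were cutadapt 1.16, STAR 2.6.0c, Cufflinks 2.2.1 and bedtools 2.27.1, with the mouse genome build mm10. The deposited gene table holds counts per Ensembl gene, as whole numbers, for 53800 genes. The tool that made these gene counts is not given in the sources used here, nor is it stated whether it counted reads by strand, so values of genes that overlap a neighbour on the other strand, as in the Hox clusters, may include reads of that neighbour. The authors also deposited FPKM values from Cufflinks for 53836 genes, which include 36 mitochondrial genes listed at 0 in every library. The mitochondrial genes are not in the count table. Another set of deposited files holds counts per exon bin, a piece of an exon that no transcript border divides, for each library. Reads outside every exon bin made up between 2.17 and 6.66 percent of the counts listed in these files, and these reads were not used. The bin counts of a library exceed its gene counts, so this is not a percent of reads.

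Gene names and positions were taken from GENCODE M21 (mm10), in which 53740 of the 53800 gene identifiers of the count table were found. Exon bins were rebuilt from the same annotation by merging the transcripts of each gene and dividing them at every exon border. The rebuilt bins matched the deposited number of bins in 51984 of 53413 genes (97.3 percent), and only these bins were given coordinates. Over 4014 genes on the minus strand, the median Spearman correlation (across bins within a gene) of counts with bin length was 0.603 in genomic order and -0.124 in reversed order, so bins were numbered in genomic order.

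Total counts per library ran from 10005867 to 30438214. The floor used for a group without counts was 3 counts over the libraries of the group, which is 0.0687 to 0.115 CPM (counts scaled to 1e+06 per library) in these groups. For a gene with 1 to 3 counts in the lower group, the ratio is given with its 95 percent counting interval. Intervals and floors cover counting error only. Values are CPM with the effective library sizes of edgeR, given as mean ± SD of 2 libraries unless stated otherwise.

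Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group, a model with 1 mean for each of the 8 groups) in R 4.3.3. The filter left 15501 of the 28342 genes with any count. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The 14 comparisons were ectoderm against mesoderm at each stage and averaged over the 4 stages, E12.5 against E9.5 and each step of 1 day within a layer, and the difference between the layers in the change from E9.5 to E12.5 (the interaction). All comparisons share 1 estimate of the spread over the 16 libraries. The p-values measure the spread between these samples, with 2 embryo batches per stage.

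Exon bins were tested with the quasi-likelihood fit and diffSpliceDGE of edgeR on 158482 bins of 12203 genes, for the average layer difference. A gene was called by its Simes p over bins, adjusted in the same way. Bin use is the percent of the counts of a gene that fall in the bin.

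Gene lists were written before the data were examined, and were tested with camera from limma 3.58.1 on voom values with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists are over the 25 lists within a comparison. The lists were the HoxA, HoxB, HoxC and HoxD clusters, surface epithelium, apical ectodermal ridge and limb ectoderm signals, limb bud mesenchyme, Hedgehog response, FGF response, WNT response, BMP response, epidermal and periderm differentiation, basement membrane and hemidesmosome, cartilage, tendon and connective tissue, muscle cells, endothelial cells, erythroid cells, macrophages, neural crest derivatives (glia and melanoblasts), cell division, dissociation and stress response, interdigit and retinoic acid, glycolysis, and heterochronic Lin28 targets. Some genes stand in more than 1 list (Egr2, Ier3, Msx1, Msx2, Bmp7 and Cyp26b1), and the glycolysis list has 18 measured members because the name Aldoa belongs to more than 1 gene identifier.

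Genes were named by a rule set before the data were examined. It takes, for the average layer difference, the change from E9.5 to E12.5 in each layer and the interaction, the 6 largest log2 fold changes in each direction among called genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups, without gene names of the Gm, Rik, AC, AL or BC kind. It also takes every Hox gene, the up to 3 members of each list with the smallest p, and the markers Epcam, Krt8, Trp63, Fgf8, Prrx1, Tbx5, Fgf10 and Shh. For exon bins it takes the 6 genes with the smallest Simes p and at least 100 counts per library, with a fixed set of known splicing targets. Genes outside this rule are said to have been chosen after their values were seen.

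The alternatives were a replicate block (the embryo batch for the layer comparisons, the replicate number for the changes over time, the interaction and the exon bins), DESeq2 1.42.0, scaling by library totals and by RLE, other count filters and none, a fold threshold of 2, fits to the compared groups alone, a test without globin genes, limma on log2 FPKM with pseudocounts of 1 and 0.1, and each library left out in turn. These were set before the data were examined. Chosen after seeing the data were the counts without ectoderm E11.5 replicate 1 set beside each count, the counts of list members by DESeq2, with the replicate block and with each library left out, the HoxC list without 3 members in the interaction, and the mesoderm genes outside the lists as a comparator for the posterior Hox genes. When a library is left out, the remaining library of its group is assumed to vary like the other groups. Scaling by library totals shifted the median of all genes by 0.17 log2 for E12.5 against E9.5 in mesoderm, by 0.10 for E10.5 against E9.5 in mesoderm and by -0.12 for the interaction. Under that scaling the genes called for E12.5 against E9.5 in mesoderm were 3182 higher and 1387 lower.

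The tests were tried on simulated data. Of 100 genes changed 2-fold at E12.5 between layers, 9 percent were called, and of 100 changed 4-fold, 71 percent, with 5 unchanged genes among 85 calls. For the average over the 4 stages these were 80 and 95 percent, with 8 unchanged genes among 183 calls. Far fewer genes were changed in these gene simulations than were called in the data, so the adjustment set a stricter p cutoff. The percents called therefore do not give the power of the real gene tests. In 3000 simulated genes with exon bins, of which 200 had a bin changed 3-fold, 92.5 percent were called when each bin kept its own dispersion, and 46 of the 231 calls (19.9 percent) were unchanged genes. With a dispersion trend shared by the bins, 97 percent were called, and 13 of 207 calls (6.28 percent) were unchanged. The exon calls therefore hold more false calls than the 5 percent aimed at. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15, and tables were read with the R package data.table (1.17.8).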

Results

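RNA was sequenced from the ectoderm and the mesoderm of the distal mouse forelimb bud at 4 stages 1 day apart, the first E9.5 and the last E12.5, with 2 libraries in each of the 8 groups. The ectoderm is the thin epithelium that covers the bud and forms the apical ectodermal ridge. The mesoderm holds the mesenchyme, the vessels and the blood. Total gene counts in ectoderm (replicate 1, replicate 2) were 10005867 and 16873358 at E9.5, 12035006 and 14398307 at E10.5. They were 24156846 and 14532373 at E11.5, and 22979717 and 14623396 at E12.5. In mesoderm they were 23101374 and 16778322 at E9.5, 30438214 and 13806300 at E10.5, then 22095984 and 13757502 at E11.5, and 23210409 and 14646672 at E12.5.

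The tissue layer was the main axis of the data. The first principal component of log2 CPM took 54.06 percent of the variance and parted the layers, the second took 17.09 percent and the third 9.106 percent. Markers of the surface epithelium stayed in the ectoderm. Epcam, an epithelial adhesion protein, stood at 270 to 490 CPM in the 8 ectoderm libraries and at 1.39 to 8.91 CPM in the 8 mesoderm libraries. Within the groups, the replicate 2 libraries differed from the replicate 1 libraries in a way that ectoderm and mesoderm shared. Pearson's r across genes, between the replicate difference in ectoderm and that in mesoderm of the same stage, was 0.546 at E9.5, 0.666 at E10.5, 0.561 at E11.5 and 0.651 at E12.5. Against mesoderm of another stage, and so of other embryo batches, r ran from 0.432 to 0.58. Much of the shared difference therefore went with the replicate number at all stages. Genes are not independent replicates.

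**Figure D1:**
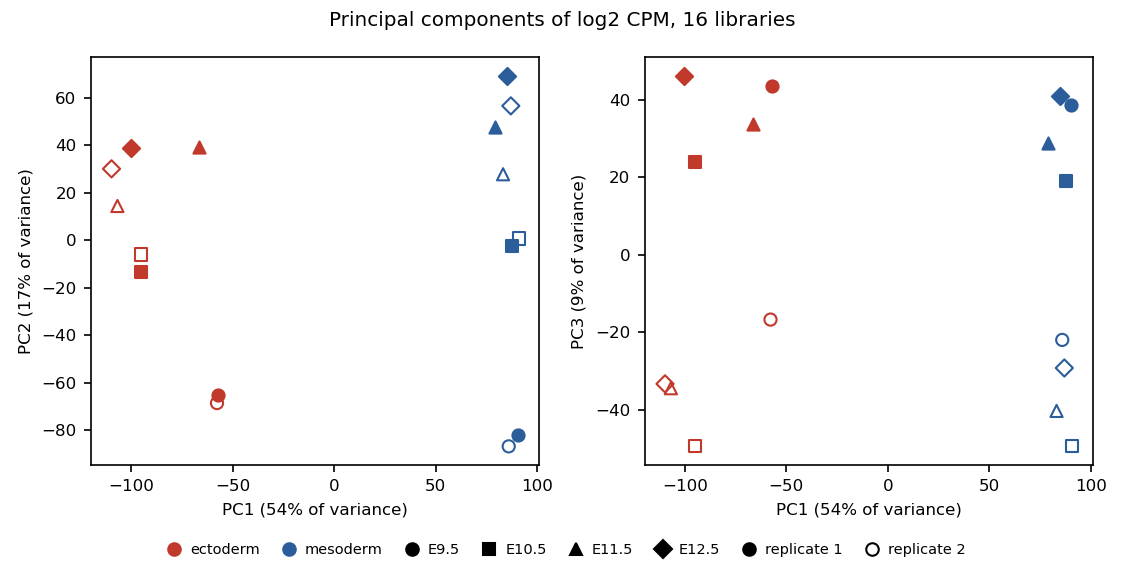
Principal components of log2 CPM of the 15501 tested genes, with 1 point per library, colour for the layer and shape for the stage. The first component takes 54.06 percent of the variance and parts ectoderm from mesoderm.

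The first comparison asked which genes set the limb ectoderm apart from the mesoderm beneath it on average over the 4 stages. It does not ask whether a gene differed at each stage. Trp63, the master regulator of stratified epithelia, was higher in ectoderm by 7.70 log2 (SE 0.19), at 473 to 701 CPM in ectoderm and 1.08 to 8.02 CPM in mesoderm (group means, n = 2 per group). Fgf8, the main growth factor of the apical ectodermal ridge, was higher by 8.08 log2 (SE 0.40). It peaked in ectoderm at E10.5 with 1250 ± 491 CPM, from 276 ± 116 CPM at E9.5 to 68.7 ± 7.26 CPM at E12.5. Wnt7a, the signal of the dorsal ectoderm, stood at 111 to 212 CPM in ectoderm and at most 1.41 CPM in mesoderm (adjusted p = 2.46e-08, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The transcription factors Sox14, Emx1 and Dlx1 and the glutathione peroxidase Gpx2 were the other genes with the largest differences in this direction, all with every ectoderm library above every mesoderm library. In the other direction, Prrx1, a transcription factor of limb mesenchyme, was lower in ectoderm (-3.47, SE 0.23). The largest differences were in genes of endothelium such as Robo4 (-6.92, SE 0.39), Cd93 (-6.66, SE 0.29), Icam2, Pcdh12 and Kcne3, with Klhl4. Averaged over the 4 stages, 7088 of 15501 genes differed between the layers, 3768 higher and 3320 lower in ectoderm, and 3654 of the genes also differed under a fold threshold of 2.

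Epithelial gene groups were higher in ectoderm nearly as a whole. In the surface epithelium list 23 of 24 measured members were higher (23 adjusted over the list alone), among them Esrp2, an epithelial splicing regulator (7.16, SE 0.18), and Spint1, an epithelial protease inhibitor (5.53, SE 0.17). In the list of ridge and limb ectoderm signals 25 of 26 were higher and 1 was lower (25 and 1 adjusted over the list alone), with Wnt4 (6.70, SE 0.17), Wnt3 (7.27, SE 0.23) and the Notch ligand Jag2 (5.68, SE 0.12) as examples. In the epidermal and periderm list 22 of 25 were higher (23 adjusted over the list alone), among them the periplakin gene Ppl (7.55, SE 0.20) and the keratin Krt7 (7.29, SE 0.26). All 16 members of the basement membrane and hemidesmosome list were higher (16 adjusted over the list alone). Examples were the laminin chain Lama5 at 672 to 1260 CPM in ectoderm and 14.8 to 28.4 CPM in mesoderm and the integrin chain Itgb4 (5.94, SE 0.18). The camera test passed for these lists (adjusted p = 9.03e-19, 2.69e-15, 5.51e-13 and 5.51e-13), and each had an adjusted p = 0.0631 with an estimated correlation.

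Genes of the cell types beneath the epithelium were lower in ectoderm. All 18 endothelial genes were lower (18 adjusted over the list alone), for example Cdh5 (-6.29, SE 0.32) and the VEGF receptor Flt1 (-3.79, SE 0.13). All 16 erythroid genes were lower (16 adjusted over the list alone), with the embryonic globin Hbb-y at -5.45 (SE 0.47) and the erythroid factor Klf1 at -3.01 (SE 0.24). So were 15 of 18 macrophage genes (16 adjusted over the list alone), such as Csf1r (-3.61, SE 0.49). Of 27 limb mesenchyme genes, 22 were lower and 3 higher (23 and 3 adjusted over the list alone). The higher ones included Meis1 and Meis2 (4.52, SE 0.23, and 4.50, SE 0.11), which mark the proximal limb. Meis2 stood at similar levels in both layers at E9.5, so its average reflects the later stages. In the Hedgehog response list 8 of 11 were lower and 0 higher (8 and 1 adjusted over the list alone), for example the co-receptor Boc (-2.24, SE 0.16) and Gli3 (-1.56, SE 0.13). The higher count was 2 without ectoderm E11.5 replicate 1 and 2 without mesoderm E11.5 replicate 2. In the cell division list 22 of 28 were lower (23 adjusted over the list alone), by small amounts such as -0.54 (SE 0.07) for Ccna2 and -0.63 (SE 0.08) for Pcna. The camera test passed for these lists (adjusted p = 1.24e-14, 6.04e-10, 3.6e-06, 4.05e-07, 0.00249 and 2.2e-06 in the order given). They had adjusted p = 0.0631, 0.123, 0.276, 0.119, 0.0631 and 0.123 with an estimated correlation.

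**Figure D2:**
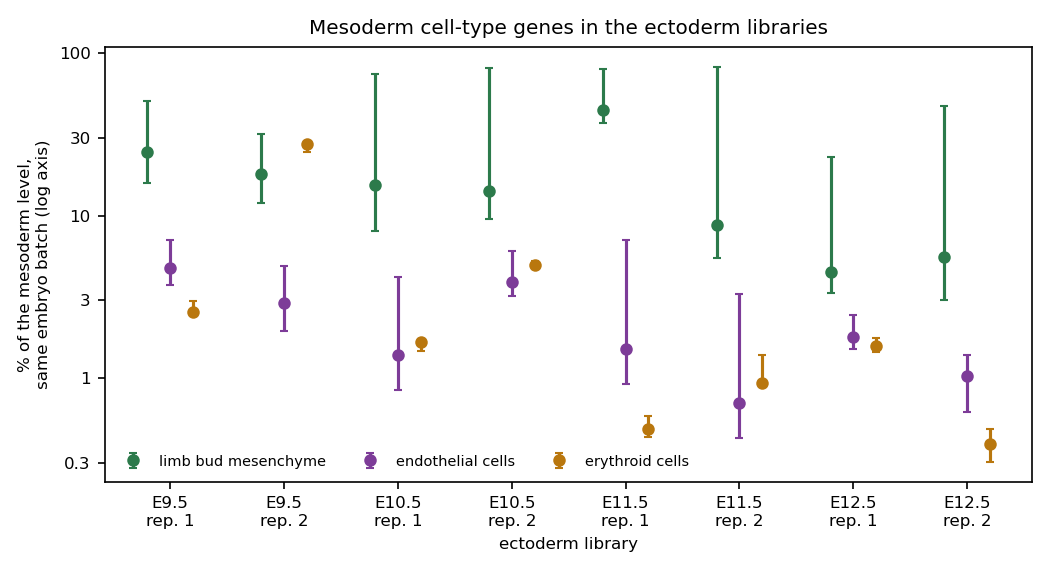
Median level of limb mesenchyme, endothelial and erythroid genes in each ectoderm library as a percent of the mesoderm library of the same embryo batch (log axis), with bars from the lower to the upper quartile over the genes. The mesenchyme genes stand highest in ectoderm E11.5 replicate 1, at 44.7 percent.

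Transcripts of 3 of these lists were measured in each ectoderm library against the mesoderm of the same batch. The median limb mesenchyme gene stood in ectoderm at 24.6 and 18.1 percent of the mesoderm level of the same embryo batch at E9.5 (replicate 1, replicate 2), 15.4 and 14.2 percent at E10.5, 44.7 and 8.74 percent at E11.5, and 4.51 and 5.55 percent at E12.5. For the median endothelial gene the percents ran from 0.704 to 4.73, and for the median erythroid gene from 0.391 to 4.95, except 27.5 percent in ectoderm E9.5 replicate 2. Without ectoderm E11.5 replicate 1, an alternative set beside these counts after seeing the data, 7272 genes differed between the layers on average. With the embryo batch as a block, 10218 genes did.

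The remaining lists were the Hox clusters and lists of signals, tissues and cell states. Of 11 HoxA genes 10 were lower in ectoderm (10 adjusted over the list alone), of 9 HoxD genes 8 were lower (8 adjusted over the list alone). Of 9 HoxC genes 7 were higher (7 adjusted over the list alone). Hoxc11 and Hoxc12 had no counts in either layer at E9.5, so their average lacks an E9.5 estimate. Both were higher in ectoderm at each later stage. The HoxA, HoxD and HoxC lists gave camera adjusted p = 0.00021, 0.000581 and 2.23e-07 and adjusted p = 0.196, 0.196 and 0.092 with an estimated correlation. Of 9 HoxB genes 4 were higher and 5 lower (camera adjusted p = 0.888), with a median of -1.10 and a mean of 0.01. The WNT response list had 9 of 17 higher and 5 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.0696), with the receptor Lgr6 (6.08, SE 0.24) and the ligase Rnf43 (5.81, SE 0.18) higher. The BMP response list had 5 of 13 higher and 3 lower (5 and 3 adjusted over the list alone, camera adjusted p = 0.402, 7 and 6 with the embryo batch as a block), with Bambi, a decoy BMP receptor, higher (1.98, SE 0.10). Cartilage genes had 5 of 20 higher and 10 lower (5 and 11 adjusted over the list alone, camera adjusted p = 0.0942). Among them Col2a1, the collagen of cartilage, was higher in ectoderm on average (3.46, SE 0.27), at 1260 ± 382 CPM against 44.5 ± 14.7 CPM at E9.5. The retinoic acid list had 5 of 15 higher and 7 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.831). The stress response list had 8 of 22 higher and 4 lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.563). Of 12 neural crest genes 2 were higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.967, 5 and 4 with the embryo batch as a block).

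Of 11 heterochronic Lin28 targets 6 were higher (6 adjusted over the list alone, camera adjusted p = 0.0982), or 3 without ectoderm E11.5 replicate 1, with the RNA-binding Lin28a at 3.39 (SE 0.47). At E9.5 Lin28a stood at similar levels in both layers, so its average reflects the later stages. The lists for FGF response (camera adjusted p = 0.402), tendon (0.55), muscle (0.888) and glycolysis (0.888) did not pass. Single members did differ, such as the FGF antagonist Il17rd (-1.67, SE 0.10), the collagen Col3a1 (-2.47, SE 0.45), the muscle intermediate filament Des (-1.66, SE 0.37) and the glucose transporter Slc2a3 (3.88, SE 0.12). The muscle list had a median of 0.16 and a mean of 0.06 with a lower direction in camera, glycolysis a median of -0.09 and a mean of 0.13, and the retinoic acid list a lower direction in camera and a higher one in fry. With an estimated correlation, camera passed 0 of 25 lists for the average over the stages (10 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, passed 20. Camera with the preset correlation passed 13 lists (5 higher and 8 lower). With the embryo batch as a block it passed 14 (6 higher and 8 lower), which held those 13.

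The same comparison was made at each stage, to follow the layers through time. Between the layers 3320 genes differed at E9.5 (2035 higher and 1285 lower in ectoderm), 4093 at E10.5 (2508 and 1585), 3196 at E11.5 (2004 and 1192) and 4099 at E12.5 (2054 and 2045). Surface epithelium genes were higher in ectoderm in 23, 23, 23 and 24 of 24 cases at the 4 stages in order (23, 23, 23 and 24 adjusted over the list alone). Basement membrane genes were higher in 14, 14, 16 and 15 of 16 (14, 15, 16 and 15 adjusted over the list alone). Ridge and limb ectoderm signals were higher in 24, 25, 24 and 19 of 26 (25, 25, 24 and 20 adjusted over the list alone). All 18 endothelial genes were lower at every stage (18 adjusted over the list alone). Cartilage genes were lower in 14 of 20 cases at E12.5 (16 adjusted over the list alone, camera adjusted p = 3.03e-08, adjusted p = 0.0579 with an estimated correlation). The calls that held with an estimated correlation were surface epithelium (adjusted p = 0.0367, 0.0471, 0.0366 and 0.042 at the 4 stages) and basement membrane (0.0367, 0.0471, 0.0324 and 0.042). Ridge signals held at the first 3 stages (0.0367, 0.0471 and 0.0407, then 0.0807), the HoxC cluster at the last 3 (0.136 at E9.5, then 0.0471, 0.0324 and 0.042), and the epidermal list at E11.5 and E12.5 (0.0407 and 0.042). The HoxB cluster held at E9.5 (0.0205), the endothelial list at E11.5 (0.0407, and 0.0502, 0.0696 and 0.0575 at E9.5, E10.5 and E12.5) and the Hedgehog list at E12.5 (0.0479). With the embryo batch as a block, the counts at the 4 stages were 6573, 7531, 6197 and 7080, of which 3303, 4078, 3192 and 4090 were among the genes above. The E9.5 count was 2117 and 2084 without ectoderm E9.5 replicate 1 or 2 and 2161 without mesoderm E9.5 replicate 1. The E10.5 count was 2692 without mesoderm E10.5 replicate 1. The E11.5 count was 1803 without ectoderm E11.5 replicate 2 and 2064 without mesoderm E11.5 replicate 2.

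The series concerns Hoxc genes in the developing integument, so the HoxC cluster (chromosome 15, from Hoxc13 at 102921103 to the end of Hoxc4 at 103036852) was followed gene by gene. From E10.5 on, all 9 Hoxc genes were higher in ectoderm than in mesoderm. At E9.5 Hoxc8, Hoxc9, Hoxc10 and Hoxc13 were (4 of 9, or 6 with the embryo batch as a block; 4, 9, 9 and 9 adjusted over the list alone at the 4 stages). At E12.5 Hoxc13 (ENSMUSG00000001655), a regulator of hair and nail keratins, stood at 114 ± 14.3 CPM in ectoderm and 0.0654 ± 0.0924 CPM in mesoderm, a ratio of 1520 (95 percent counting interval 521 to 7390, adjusted p = 7.5e-07). Hoxc12 had a ratio of 1090 (302 to 9030). Hoxc10, Hoxc9 and Hoxc8, without counts in mesoderm at E12.5, were at least 562-fold, at least 262-fold and at least 101-fold higher. The anterior genes Hoxc4, Hoxc5 and Hoxc6 were abundant in both layers at E9.5 and were not called between them without a block, with Hoxc5 at 130 ± 1.87 CPM in ectoderm and 64.2 ± 2.24 CPM in mesoderm (adjusted p = 0.18), and Hoxc4 at 27.1 ± 0.893 and 39 ± 4 CPM (adjusted p = 0.478). With the embryo batch as a block, Hoxc5 (1.02, adjusted p = 0.00081) and Hoxc6 (0.70, adjusted p = 0.0264) were higher in ectoderm. Hoxc8 was already higher at E9.5, at 74.9 ± 6.55 against 4.05 ± 0.078 CPM (adjusted p = 0.000101). Hoxc10 at E9.5 rested on 12 counts in ectoderm and 0 in mesoderm, at least 5.71-fold.

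**Figure D3:**
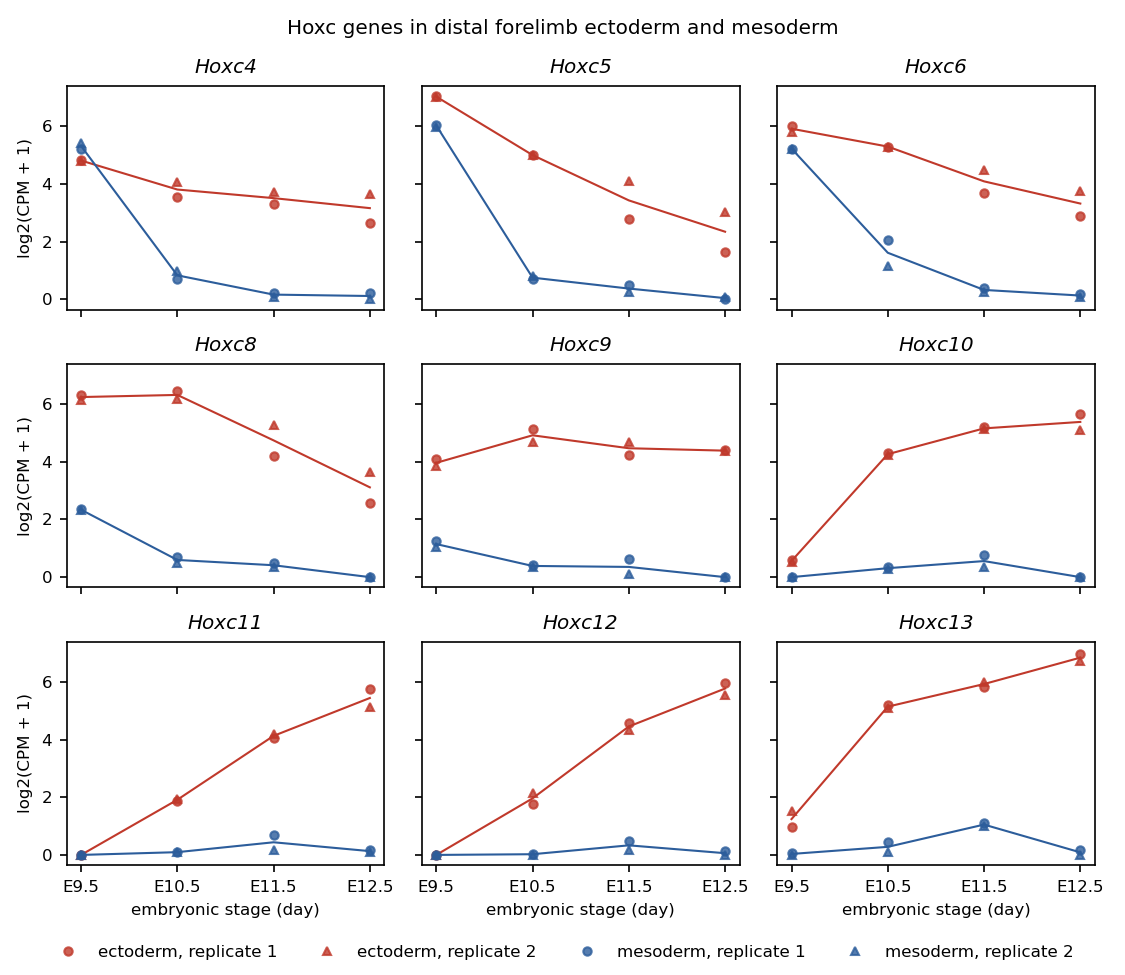
Levels of the 9 Hoxc genes as log2(CPM + 1) against embryonic stage, with 1 point per library and lines through the group means of ectoderm and mesoderm. In ectoderm Hoxc10 to Hoxc13 rise from at most 1.41 CPM at E9.5 to 41.4 to 114 CPM at E12.5, while Hoxc4 to Hoxc8 fall in both layers.

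The other Hox clusters differed from HoxC. HoxA genes were lower in ectoderm in 6, 8, 6 and 9 of 11 cases at the 4 stages (7, 9, 8 and 9 adjusted over the list alone). HoxD genes were lower in 5, 6, 4 and 6 of 9 cases (7, 6, 6 and 6 adjusted over the list alone). The posterior genes of both clusters, which pattern the hand plate, were far lower in ectoderm at E12.5, with Hoxa13 at 6.18 ± 0.0627 against 226 ± 24.9 CPM and Hoxd13 at 21.3 ± 5.49 against 825 ± 308 CPM. In the HoxB cluster 5 of 9 genes were lower in ectoderm at E9.5 (7 adjusted over the list alone), and Hoxb1 to Hoxb4 were higher at E10.5, E11.5 and E12.5 (5, 4 and 4 genes adjusted over the list alone), though at no more than 14.7 CPM. Meanwhile 4 genes (Hoxb5, Hoxb7, Hoxb8 and Hoxb9) were lower at E12.5 (5 adjusted over the list alone), at only 0.222 to 2.08 CPM in mesoderm. Hoxb5 and Hoxb8 rested there on 9 and 30 counts in mesoderm and 0 in ectoderm. The Hoxb1 calls at E10.5, E11.5 and E12.5 rested on 12, 9 and 11 counts in ectoderm and 0 in mesoderm. The HoxA count was 3 at E9.5 without ectoderm replicate 2, 4 at E10.5 without ectoderm replicate 1 and 5 without mesoderm replicate 2. It was 3 at E11.5 without ectoderm replicate 2 and 2 without mesoderm replicate 2, and 5 at E12.5 without ectoderm replicate 1, ectoderm replicate 2 or mesoderm replicate 2. The HoxD count was 2 at E9.5 without ectoderm replicate 1 or 2 and 3 without mesoderm replicate 1. At E11.5 it was 2 without ectoderm replicate 2, 1 without mesoderm replicate 1 and 0 without mesoderm replicate 2. The HoxB counts were 3 lower at E9.5 without ectoderm replicate 2, 2 higher at E10.5 without ectoderm replicate 2, and 2 higher at E11.5 without ectoderm replicate 2 or mesoderm replicate 2.

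The next comparison asked how the ectoderm changed from E9.5 to E12.5. Limb tips were taken at every stage, so a change between stages in either layer may also reflect the region or the mix of cells sampled. Hoxc10 to Hoxc13 and genes of epithelia such as Dsg3 rose, while Lin28a and Cdx1 fell. Gabrp, a GABA receptor subunit of epithelia, rose from 0.158 to 277 ± 11.7 CPM, a ratio of 2420 (counting interval 828 to 11700), the desmosomal cadherin Dsg3 by a ratio of 1060 (189 to 41800), Anxa1 by 707 (242 to 3430), and the hair keratin Krt35 at least 139-fold. Lin28a, an RNA-binding protein that blocks let-7 maturation in early embryos, fell from 415 ± 64.8 to 3.1 ± 3.54 CPM (-7.13, SE 0.83, adjusted p = 0.000211), and Cdx1, a regulator of anterior Hox genes, fell at least 382-fold. Other genes with the largest falls were Wfikkn1 and Igdcc3. The globin Hbb-bh1 also fell, from 26.6 and 184 CPM in the 2 ectoderm libraries of E9.5, which is 2.48 and 28.7 percent of the mesoderm level. In total 2495 genes changed, 1410 up and 1085 down.

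Hoxc13, Hoxc12, Hoxc11 and Hoxc10 rose in ectoderm. Hoxc13 went from 1.41 ± 0.651 CPM at E9.5 through 34.3 ± 1.52 and 59.9 ± 5.12 to 114 ± 14.3 CPM (6.27, SE 0.47, adjusted p = 1.92e-05). Hoxc10 went from 0.475 ± 0.0744 to 41.4 ± 11 CPM (6.46, SE 0.42, adjusted p = 2.69e-05). Hoxc12 and Hoxc11, without counts at E9.5, stood at 54.1 ± 11.2 and 43.5 ± 13.4 CPM at E12.5, for Hoxc12 a rise of at least 482-fold. Hoxc5, Hoxc8, Hoxc6 and Hoxc4 fell, Hoxc5 from 130 ± 1.87 to 4.67 ± 3.56 CPM (-4.82, adjusted p = 0.000277) and Hoxc8 from 74.9 ± 6.55 to 8.26 ± 4.63 CPM (-3.19, adjusted p = 0.000857). The Hoxc4 call (adjusted p = 0.0268) was lost without ectoderm E9.5 replicate 1 (0.107), ectoderm E9.5 replicate 2 (0.101) or ectoderm E12.5 replicate 1 (0.187). Hoxc9 stood at 14.7 ± 1.91 and 19.9 ± 0.528 CPM and was not called (adjusted p = 0.556). The HoxC list thus had 4 of 9 up and 4 down (4 and 4 adjusted over the list alone). All 9 HoxB genes fell (9 adjusted over the list alone, camera adjusted p = 1.07e-12), the only list that held with an estimated correlation in ectoderm (adjusted p = 0.00268).

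Of 25 epidermal and periderm genes 19 rose and 0 fell in ectoderm (22 and 0 adjusted over the list alone, camera adjusted p = 2.47e-17, adjusted p = 0.0596 with an estimated correlation). Among them was the envelope protein Evpl (4.04, SE 0.39). The connexin Gjb2, which belongs to the ridge and limb ectoderm list, rose from 3.14 ± 1.37 to 288 ± 71.5 CPM. Of 16 basement membrane genes 8 rose (11 adjusted over the list alone, camera adjusted p = 2.22e-06, adjusted p = 0.195 with an estimated correlation). They included the hemidesmosomal collagen Col17a1 from 32.2 ± 11.4 to 1180 ± 120 CPM and the anchoring fibril collagen Col7a1 from 3.9 ± 0.29 to 186 ± 11 CPM. Of 8 muscle genes 5 fell (6 adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.0596 with an estimated correlation), from low levels such as 3.83 ± 1.15 CPM for Des. Of 27 limb mesenchyme genes 12 fell and 1 rose (15 and 2 adjusted over the list alone, camera adjusted p = 9.66e-05, adjusted p = 0.268 with an estimated correlation). Of 16 erythroid genes 9 fell (12 adjusted over the list alone, camera adjusted p = 0.000184, adjusted p = 0.432 with an estimated correlation). Mesoderm genes outside the lists stood in these ectoderm libraries at a median of 13.1 and 10.9 percent of the mesoderm level at E9.5 and 4.45 and 4.35 percent at E12.5. These genes were chosen as called and lower in ectoderm by more than 2 log2 at every stage other than E11.5. Low percents at E9.5 and E12.5 therefore follow from the choice. The retinoic acid enzymes changed in opposite directions, Cyp26b1 falling from 403 ± 54.4 to 36.6 ± 3.41 CPM (adjusted p = 3.61e-05) and Cyp26a1 rising from 6.81 ± 1.11 to 97.1 ± 24.8 CPM (adjusted p = 0.000136). Sp9, a regulator of the ridge, rose from 0.43 ± 0.16 to 51.2 ± 13.2 CPM (adjusted p = 3.85e-05).

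The ectoderm count of 2495 was 5480 with the replicate number as a block (2494 of them shared), and 1264, 1110, 1248 and 1550 without E9.5 replicate 1, E9.5 replicate 2, E12.5 replicate 1 and E12.5 replicate 2 of the ectoderm. Without E9.5 replicate 2, 9 epidermal genes, 5 basement membrane genes and 2 erythroid genes were called. The erythroid count was 2 without E12.5 replicate 1 and 4 without E12.5 replicate 2. The mesenchyme count was 5 without E12.5 replicate 1, 6 without E12.5 replicate 2 and 5 without E9.5 replicate 1. Its single riser was not called without E9.5 replicate 2 or E12.5 replicate 1. There were 2 risers without E11.5 replicate 1 or E11.5 replicate 2 of the ectoderm.

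The corresponding comparison was made in mesoderm, where Meis1, Meis2 and Lin28a fell and Dlx5 rose. Meis2 and Meis1, which mark the proximal limb, fell by 8.43 (SE 0.27, adjusted p = 3.57e-08) and by 7.33 on the log2 scale, Meis2 from 259 ± 28.8 to 0.754 ± 0.142 CPM. Lin28a fell from 412 ± 63.4 to 0.0523 ± 0.0123 CPM, a ratio of 8000 (counting interval 2210 to 66100), and Lbx1, a factor of migrating muscle precursors, fell at least 300-fold, beside Igdcc3 and the kinase Pkdcc. Dlx5, a homeobox gene of skeletal and ridge development, rose from 0.376 ± 0.00928 to 82 ± 10.1 CPM (7.74, SE 0.30, adjusted p = 1.57e-07). The long noncoding RNA Hottip at the end of the HoxA cluster, the activin subunit Inhba, Dbx2, Atp6v1g3 and the macrophage gene Mpeg1, each without counts at E9.5, rose at least 540-fold, 368-fold, 367-fold, 294-fold and 207-fold, and Tfap2b rose by 10.24 (SE 0.64). In total 4589 genes changed, 2635 up and 1954 down.

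Of 20 cartilage genes 14 rose and 1 fell in mesoderm (16 and 2 adjusted over the list alone, camera adjusted p = 1.43e-06, adjusted p = 0.126 with an estimated correlation). Examples were Col9a3 (6.90, SE 0.58), the sulfation enzyme Papss2 (5.66, SE 0.47) and the joint factor Gdf5, from 0.109 ± 0.0194 to 57 ± 42.6 CPM. Of 18 macrophage genes 17 rose (17 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.34 with an estimated correlation), such as Csf1r (5.75, SE 0.93) and Cx3cr1 (6.22, SE 0.93). Of 8 muscle genes 7 fell (7 adjusted over the list alone, camera adjusted p = 3.89e-06, adjusted p = 0.0121 with an estimated correlation), with Des from 23.4 ± 7.05 to 0.179 ± 0.00612 CPM. Of 11 Lin28 targets 10 fell (10 adjusted over the list alone, camera adjusted p = 4.33e-08, adjusted p = 0.0734 with an estimated correlation), among them Lin28b (-6.64, SE 0.79) and Hmga2 (-2.66, SE 0.27). Of 12 neural crest genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00553, adjusted p = 0.0734 with an estimated correlation), with Edn3 (1.86, SE 0.24) and Tubb3 (2.87, SE 0.55). Of 13 BMP response genes 9 rose (9 adjusted over the list alone, camera adjusted p = 0.000262, adjusted p = 0.34 with an estimated correlation), with the BMP effector Smad9 (2.48, SE 0.40) and Bambi (1.48, SE 0.19). Of 18 glycolysis genes 11 fell and 0 rose (12 and 1 adjusted over the list alone, camera adjusted p = 4.31e-05, adjusted p = 0.363 with an estimated correlation), such as Hk2 (-1.59, SE 0.18) and Pdk1 (-1.58, SE 0.16).

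All 9 HoxB genes fell in mesoderm as well (9 adjusted over the list alone, camera adjusted p = 5.76e-12, adjusted p = 0.00227 with an estimated correlation). HoxB and muscle were the lists that held with an estimated correlation. Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9 fell and 0 Hoxc genes rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.00867, adjusted p = 0.34 with an estimated correlation), Hoxc5 by a ratio of 2530 (counting interval 454 to 1e+05). Hoxa13 rose from 0.44 ± 0.188 to 226 ± 24.9 CPM (adjusted p = 7.91e-05) and Hoxd13 from 9.24 ± 1.25 to 825 ± 308 CPM (adjusted p = 0.000279). In the HoxA cluster as a whole 7 of 11 genes fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.351 with an estimated correlation). In the HoxD cluster 5 of 9 genes fell and 3 rose (5 and 3 adjusted over the list alone, camera adjusted p = 0.118). The HoxA count of falls was 3 without mesoderm E12.5 replicate 1 or mesoderm E9.5 replicate 1 and 4 without mesoderm E9.5 replicate 2. Its count of rises was 1 without any single library of E9.5, E10.5 or E12.5. The mesoderm count of 4589 was 7987 with the replicate number as a block (4587 of them shared), 2861 without mesoderm E9.5 replicate 1 and 2773 without mesoderm E12.5 replicate 1. The macrophage count was 9 without mesoderm E12.5 replicate 1, 9 without mesoderm E9.5 replicate 1 and 11 without mesoderm E9.5 replicate 2. The BMP count was 5 without mesoderm E12.5 replicate 1. The glycolysis count was 7 without mesoderm E12.5 replicate 2 or mesoderm E9.5 replicate 1. The rising count was 2 without mesoderm E12.5 replicate 2 and 1 without ectoderm E11.5 replicate 1 or 2.

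The interaction asked which changes from E9.5 to E12.5 differed between the layers. Meis2 fell in mesoderm but stood at 231 ± 2.13 and 155 ± 1.58 CPM in ectoderm (difference of the changes 7.85 log2, SE 0.31, adjusted p = 4.31e-07), and Meis1 behaved alike (6.08, SE 0.63, adjusted p = 0.00028). The retinoic acid degrading enzymes moved in opposite ways, with Cyp26b1 falling in ectoderm and rising in mesoderm from 26.5 ± 4.53 to 539 ± 99.7 CPM (-7.81, SE 0.43, adjusted p = 5.16e-06) and Cyp26a1 rising in ectoderm alone (adjusted p = 0.000488). Dlx5 rose in mesoderm and stood at 67.6 ± 6.84 and 74.4 ± 6.6 CPM in ectoderm (-7.60, SE 0.35, adjusted p = 1.32e-06), as did its neighbour Dlx6 (adjusted p = 0.000117). Foxj1, a regulator of cilia, fell in ectoderm from 28.7 ± 5.28 to 0.401 ± 0.179 CPM and was at most 0.754 CPM in mesoderm (adjusted p = 8.25e-05). The protease Mmp28 fell in ectoderm from 11.4 ± 1.95 to 0.262 ± 0.277 CPM and rose in mesoderm from 1.31 ± 0.0325 to 15 ± 1 CPM (adjusted p = 0.000117). Snx31 and Sh2d4a rose in ectoderm, to 11.1 ± 1.82 and 12.2 ± 1.88 CPM, and were at most 0.396 CPM in mesoderm (adjusted p = 0.00122 and 0.000627). In total 1282 genes differed, 484 with the higher change in ectoderm and 798 with the lower.

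In the HoxC cluster 5 of 9 genes (Hoxc4, Hoxc5, Hoxc6, Hoxc8 and Hoxc9) fell less or did not fall in ectoderm (5 adjusted over the list alone, camera adjusted p = 8.82e-11, adjusted p = 0.0345 with an estimated correlation). No other list passed with an estimated correlation. Without Hoxc10, Hoxc11 and Hoxc12, for which the interaction could not be estimated, the HoxC list passed with the preset correlation (camera adjusted p = 4.41e-07) but not with an estimated one (camera adjusted p = 0.0838), a test chosen after seeing the data. For Hoxc4 the difference was 6.84 (SE 0.82, adjusted p = 0.000622). For Hoxc10, Hoxc11 and Hoxc12, without counts in mesoderm at E9.5, the interaction could not be estimated, and for Hoxc13, with 1 and 3 counts in mesoderm at E9.5 and E12.5, it was not called (adjusted p = 0.279). Hoxb1 to Hoxb4 (4 of 9 HoxB genes, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0634) also fell less in ectoderm, while the median of the list was -0.67 and its mean 0.65. Of 20 cartilage genes 9 had the lower change in ectoderm (13 adjusted over the list alone, 14 with the replicate number as a block, camera adjusted p = 1.58e-10, adjusted p = 0.0838 with an estimated correlation). Among them was Sox9, the master regulator of cartilage, from 64.1 ± 5.82 to 24.7 ± 0.194 CPM in ectoderm and from 31.9 ± 2.13 to 315 ± 88.5 CPM in mesoderm (adjusted p = 0.000633). Others were Col9a3 (adjusted p = 0.000259), Sox5 (adjusted p = 0.000649) and Gdf5 (adjusted p = 0.00215). Of 25 epidermal genes 4 rose more in ectoderm (5 adjusted over the list alone, camera adjusted p = 1.39e-05, adjusted p = 0.262 with an estimated correlation), such as Evpl (adjusted p = 5e-04). Of 12 neural crest genes 5 had the lower change in ectoderm (5 adjusted over the list alone, camera adjusted p = 0.00375, adjusted p = 0.0838 with an estimated correlation), such as the endothelin receptor Ednrb (-3.52, SE 0.43, adjusted p = 0.000685). In the BMP list 5 of 13 had the lower change (7 adjusted over the list alone, 8 with the replicate number as a block, camera adjusted p = 3.14e-05, adjusted p = 0.215 with an estimated correlation). Bmp2, which belongs to the ridge and limb ectoderm list, had the lower change in ectoderm as well (edgeR, adjusted p = 7.18e-05). It rose in mesoderm from 1.58 ± 0.547 to 52.7 ± 11.8 CPM. Hmga2 fell in mesoderm and was not called lower in ectoderm (2.95, SE 0.36, adjusted p = 0.000652).

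The interaction count was 3588 with the replicate number as a block (1281 of them shared), 1679 with the higher change in ectoderm and 1909 with the lower. It was 733 and 717 without ectoderm E9.5 replicate 1 or 2, 649 without ectoderm E12.5 replicate 1, 731 and 767 without mesoderm E9.5 replicate 1 or 2, and 787 without mesoderm E12.5 replicate 1. The HoxC count was 3 without mesoderm E12.5 replicate 1, where Hoxc5 (adjusted p = 0.0804) and Hoxc8 (0.152) were not called. Hoxc8 was also lost without ectoderm E9.5 replicate 1 or 2 (0.0616 and 0.0721), mesoderm E9.5 replicate 1 or 2 (0.0737 and 0.0694) and mesoderm E12.5 replicate 2 (0.0952). In limma on FPKM values some of these calls were lost. With a pseudocount of 1 these were Hoxc5 (0.10, adjusted p = 0.958), Hoxc8 (-1.51, 0.0754) and Hoxc9 (0.87, 0.0502), and without a filter also Hoxc6 (1.66, 0.0665). With a pseudocount of 0.1 they were Hoxc5 (2.40, adjusted p = 0.0638) and Hoxc8 (0.88, 0.508). With only the groups compared, edgeR lost Hoxc8 (adjusted p = 0.0581). The HoxB count was 2 without ectoderm E12.5 replicate 1, ectoderm E9.5 replicate 1 or mesoderm E9.5 replicate 2. The BMP count was 2 without ectoderm E12.5 replicate 1 or 2, ectoderm E9.5 replicate 2, mesoderm E12.5 replicate 1 or mesoderm E9.5 replicate 1, and 3 without mesoderm E9.5 replicate 2.

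The steps of 1 day asked when the changes fell. In ectoderm 641 genes changed from E9.5 to E10.5 (458 up and 183 down), and in mesoderm 1433 did (821 up and 612 down). The balance in mesoderm moved with the setting, to 1070 up and 504 down with library totals and 2127 up and 2170 down with the replicate number as a block. From E10.5 to E11.5 edgeR called 1 gene in ectoderm, Gpr4, a proton-sensing receptor named after its value was seen, from 1.65 ± 0.208 to 8.98 ± 0.591 CPM (2.43, SE 0.26, adjusted p = 0.019), with 1209 genes at an unadjusted p under 0.05 and 222 called by DESeq2. In mesoderm 61 genes were called for that step (43 up and 18 down). From E11.5 to E12.5 edgeR called 66 genes in ectoderm (18 up and 48 down) and 48 in mesoderm (23 up and 25 down). DESeq2 called 418 in ectoderm (139 up and 279 down) and 404 in mesoderm (249 up and 155 down). The balance of this step moved in limma on log2(FPKM + 1), to 83 up and 46 down in ectoderm and 77 up and 17 down in mesoderm. In ectoderm Hoxc13 rose in the first step, from 1.41 ± 0.651 to 34.3 ± 1.52 CPM (4.54, SE 0.45, adjusted p = 0.000472). Hoxc8 was not called in any of the 3 ectoderm steps (adjusted p = 0.978, 0.259 and 0.126).

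These step counts moved with the libraries and the settings used. With the replicate number as a block they were 2371, 434 and 565 in ectoderm and 4297, 746 and 805 in mesoderm, in order of stage, and these held 641, 1 and 66 and 1433, 61 and 48 of the genes above. The first ectoderm step gave 218, 145, 279 and 221 genes without E9.5 replicate 1, E9.5 replicate 2, E10.5 replicate 1 and E10.5 replicate 2 of the ectoderm, and the first mesoderm step gave 614, 778, 637 and 703 without the same libraries of the mesoderm. The second ectoderm step gave 153 genes without ectoderm E11.5 replicate 2, 1 without either mesoderm E9.5 library and 0 without any other library. The third ectoderm step gave 252 genes without ectoderm E11.5 replicate 2, 34 without ectoderm E11.5 replicate 1, 0 and 22 without ectoderm E12.5 replicate 1 and 2, 32 without either ectoderm E9.5 library, 33 and 35 without ectoderm E10.5 replicate 1 and 2. It gave 36 and 29 without mesoderm E9.5 replicate 1 and 2, 29 without either mesoderm E10.5 library and 43 without either mesoderm E11.5 library. The second mesoderm step gave 7 genes without either ectoderm E9.5 library, 12 without either ectoderm E10.5 library, 96 without ectoderm E11.5 replicate 2, and 9 without either mesoderm E9.5 library. It gave 1 and 7 without mesoderm E10.5 replicate 1 and 2, and 0 and 115 without mesoderm E11.5 replicate 1 and 2. The third gave 18 without either ectoderm E9.5 library, 15 and 22 without ectoderm E10.5 replicate 1 and 2, and 25 without either mesoderm E9.5 library. It gave 23 and 6 without mesoderm E11.5 replicate 1 and 2, and 0 and 131 without mesoderm E12.5 replicate 1 and 2.

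The exon bins asked whether the layers use different exons of the same genes. In Fgfr2, the receptor for limb FGFs, the bin at chromosome 7, 130199758 to 130199905, took 2.96 ± 0.34 percent of the counts of the gene in ectoderm and 0.251 ± 0.23 percent in mesoderm (SD, n = 8 libraries per layer), and the neighbouring bin at 130198419 to 130198563 took 0.152 ± 0.11 percent in ectoderm and 3.1 ± 0.75 percent in mesoderm (Simes adjusted p = 2.72e-24, edgeR). Epithelium and mesenchyme are known to use different exons of this receptor, which set its choice of ligand. In Dnmbp, a scaffold of cell junctions, 1 bin (chromosome 19, 43889310 to 43890691) took 14 ± 2 percent in ectoderm and 0.178 ± 0.099 percent in mesoderm (edgeR, Simes adjusted p = 1.46e-67). In Enah, an actin regulator with a known epithelial exon, the bin at chromosome 1, 181911597 to 181911659, took 2 ± 0.39 against 0.0472 ± 0.022 percent (edgeR, Simes adjusted p = 3.45e-36).

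The other genes with the smallest p-values were Epb41l5 and Epb41 (membrane skeleton), Amotl1 (tight junctions), Agap3 and Fgfr1, in which the bin at chromosome 8, 25563374 to 25563524, took 1.83 ± 0.82 against 0.048 ± 0.056 percent. Among the known splicing targets the layers also differed in Cd44, with 7 bins of higher use in ectoderm (edgeR, Simes adjusted p = 5.12e-08), Lef1 (1.19e-24), Itga6 (1.66e-19), Arhgef11 (3.16e-12), Ctnnd1 (1.31e-10), Slk (4.15e-08) and Macf1 (0.000116). Esrp1, Numb, Tcf7l2 and Mbnl1 were not called (edgeR, Simes adjusted p = 1 for each). In total 196 of 12203 genes were called, and 426 bins, 253 with higher and 173 with lower use in ectoderm. The F test over all bins of a gene called 232 genes, and with the replicate number as a block 411 genes were called, which held all 196. Fewer were called with stricter filters, 144 genes with at least 10 counts in at least 8 libraries (140 of them shared) and 59 genes with a bin mean of at least 50 counts (56 of them shared). On simulated data with the dispersion of each bin 19.9 percent of the calls were false.

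**Figure D4:**
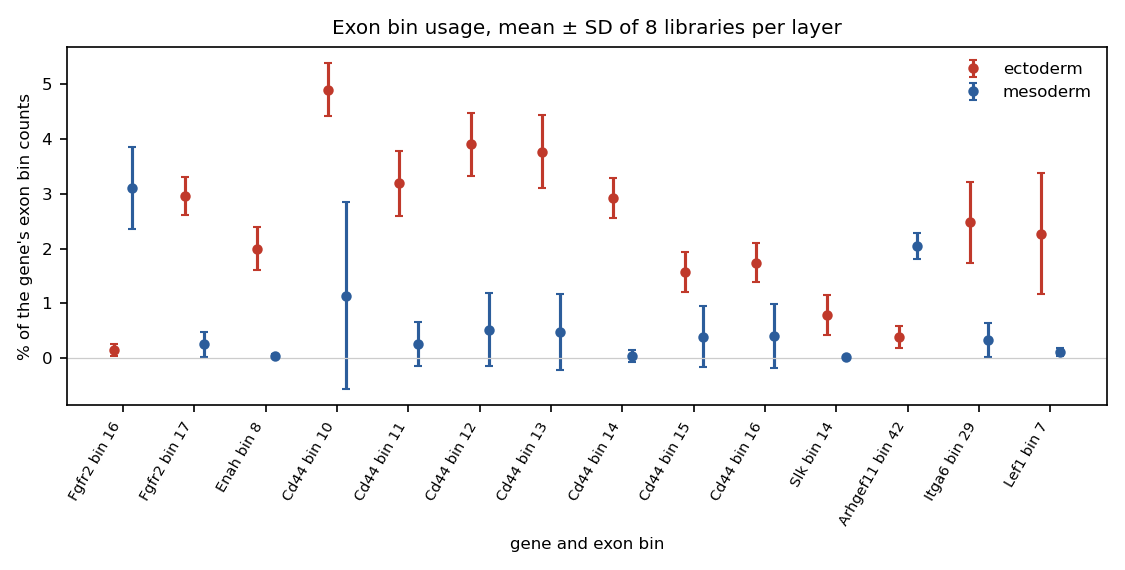
Share of the counts of a gene in named exon bins, as mean and SD of 8 ectoderm and 8 mesoderm libraries, in percent. The Fgfr2 bins exchange places, with bin 17 at 2.96 percent in ectoderm and bin 16 at 3.1 percent in mesoderm.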

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

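For these results, the tests of whole mesoderm tissue, of the RNA extraction kit, of the posterior Hox genes (with both comparators) and of the other splits of the samples were chosen only after the result was seen. The tests of limb mesenchyme cells, gene length and sex were written down before it.

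The change from E9.5 to E12.5 differed between ectoderm and mesoderm, by the test of the difference itself, in 1282 genes. Among the named genes these were Snx31 (9.38 log2, adjusted p = 0.00122), AU018091 (8.64, adjusted p = 0.041), Sh2d4a (8.40, adjusted p = 0.000627), Meis2 (7.85, adjusted p = 4.31e-07), Cyp26a1 (7.63, adjusted p = 0.000488), Meis1 (6.08, adjusted p = 0.00028), Evpl (4.78, adjusted p = 5e-04) and Hmga2 (2.95, adjusted p = 0.000652), with the higher change in ectoderm. With the lower change in ectoderm they were Gdf5 (-8.80, adjusted p = 0.00215), Mmp28 (-8.80, adjusted p = 0.000117), Dlx6 (-8.65, adjusted p = 0.000117), Foxj1 (-8.60, adjusted p = 8.25e-05), Cyp26b1 (-7.81, adjusted p = 5.16e-06), Dlx5 (-7.60, adjusted p = 1.32e-06), Col9a3 (-7.00, adjusted p = 0.000259), Bmp2 (-6.09, adjusted p = 7.18e-05), Sox9 (-4.68, adjusted p = 0.000633), Ednrb (-3.52, adjusted p = 0.000685) and Sox5 (-3.29, adjusted p = 0.000649). In the HoxC cluster 5 genes differed, Hoxc9 (adjusted p = 0.00272), Hoxc4 (0.000622), Hoxc5 (0.0113), Hoxc6 (0.00132) and Hoxc8 (0.0333), and 4 differed in the HoxB cluster, 9 in the cartilage list, 5 in the neural crest list, 5 in the BMP response list and 4 in the epidermal list. The AU018091 call was lost with only the groups compared (8.595 log2, edgeR adjusted p = 0.0797). It was also lost without ectoderm E9.5 replicate 1 or 2 (8.762 and 8.516 log2) and ectoderm E10.5 replicate 1 or 2 (8.665 and 8.649). The same held without ectoderm E12.5 replicate 1 or 2 (8.531 and 8.73), mesoderm E9.5 replicate 2 (6.349) and mesoderm E12.5 replicate 1 or 2 (8.613 and 8.642). The libraries that move the other calls and counts are named with the interaction in the report. In the exon files, reads outside every annotated bin made up at most 6.66 percent of the counts listed for a library, and they were not used in any comparison.

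Genes of limb mesenchyme stood at 44.7 percent of the mesoderm level in ectoderm E11.5 replicate 1 and at 8.74 percent in replicate 2. Whole mesoderm tissue carried over is argued against, since it would bring endothelial and erythroid transcripts in the same share, and the larger of their median percents in that library was 1.5. Limb mesenchyme cells carried over remain a candidate explanation, since mesoderm genes outside the lists were also higher in replicate 1, by a ratio of 3.33 to replicate 2. No biological explanation was tested, because both libraries come from the same stage and tissue.

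The replicate 2 libraries differed from the replicate 1 libraries in 8106 genes over all groups (3919 higher, 4187 lower). Sex of the pooled embryos as the whole cause is argued against, since the median log2 difference of 4 Y-linked genes was 0.60 while Xist, from the inactive X chromosome of females, was also higher in replicate 2, at 236 to 1150 CPM against 14 to 55.1 CPM. Kdm5d was not called (edgeR, adjusted p = 0.0545), and Ddx3y, Eif2s3y and Kdm5d were lower in replicate 2 in ectoderm E11.5. In mesoderm E11.5 Kdm5d was also lower in replicate 2 (19 against 22.7 CPM), and Ddx3y stood at 22.7 CPM in both replicates. Other noncoding RNAs rose with Xist, by 4.09 log2 for Neat1, 2.84 for Meg3, 2.12 for Kcnq1ot1 and 2.07 for Malat1. Gene length may contribute, since the difference rose with transcript length (Spearman's rho 0.314 over 15494 genes, which are not independent). Embryo batches that differ by stage are argued against as the whole cause, since other stages shared the difference. Pearson's r across genes was 0.432 to 0.58 between ectoderm and mesoderm of another stage. The RNA extraction kit cannot be told apart from other factors that went with the replicate number. Each kit was used for 1 replicate number only. No biological explanation other than sex was tested.

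Posterior Hoxa and Hoxd genes were measured in ectoderm below their mesoderm level. They stood at 28.6 to 59 percent of it in ectoderm E11.5 replicate 1 and at 3.44 to 9.27 percent in replicate 2. Limb mesenchyme cells carried over stay open as the source. Of the 64 pairs of gene and library 0 percent lay above 2 times the mesenchyme percent of the same library, but 23 lay more than 2-fold below it, outside the range that carry-over alone was set to give (median ratio 0.603). Some genes of that list stood near the mesoderm level in both E11.5 ectoderm libraries (upper quartiles 79.5 and 82.6 percent). Its median may therefore overstate a carried share. Against mesoderm genes outside the lists 1 pair lay above 2 times the percent (Hoxd9 in ectoderm E11.5 replicate 1, ratio 2.63), 11 lay more than 2-fold below it, and the median ratio was 0.794. The genes outside the lists were chosen for low levels in ectoderm at every stage other than E11.5, so only their E11.5 percents are free of that choice. Expression in the ectoderm itself stays open too, because none of these values excludes it.

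The real layers gave more genes than any other split tried, but this cannot measure chance. The other splits carry the layer difference in their spread, which by itself keeps most of their counts low. The splits were tested in a model with stage and 1 layer effect, so the real layers gave 6934 genes, and 192 for exon use, rather than the 7088 and 196 of the report. Of 100 splits of the 16 libraries 1, the real one, gave as many genes (4347 for the highest other), and of the 27 other splits that part all 8 embryo batches the highest gave 2368. The splits with 4347 and 2368 genes each exchanged 1 ectoderm and 1 mesoderm library of a single stage, another such split gave 0 genes, and all other splits, which carry the layer difference in their spread, gave at most 1 gene. For exon use 1 of 24 splits gave as many genes (36 for the highest other), but only 5 of the others part all 8 batches (highest 9), too few for a share under 0.05.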

How the results depend on the processing

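The alternatives were set before the data were examined, with exceptions chosen only after the data were seen. These were the counts without ectoderm E11.5 replicate 1 set beside each count and the counts of list members under DESeq2, the replicate block and each library left out. The HoxC list without 3 members in the interaction and the mesoderm genes outside the lists as a comparator for the posterior Hox genes were exceptions too. Of the alternatives tried on 444 results for named genes, 11398 values kept their direction and side of the threshold, 468 no longer passed it and 3 changed sign. Hoxc8 in the interaction went to -1.51 (adjusted p = 0.0754) in limma on log2(FPKM + 1) and to -1.51 (adjusted p = 0.138) there without a filter, and Hbb-bt in the interaction to 1.38 (adjusted p = 0.94) without ectoderm E9.5 replicate 2, the highest of a range that began at -9.64 without ectoderm E12.5 replicate 1. In limma on log2(FPKM + 1) without a filter Hoxc13 at E9.5 (0.53, adjusted p = 0.0629), Hoxc10 at E9.5 (0.27, adjusted p = 0.488), Hoxc5 at E12.5 (1.11, adjusted p = 0.062) and Hoxc9 over time in mesoderm (-0.47, adjusted p = 0.163) were not called, and with the filter Hoxc10 (adjusted p = 0.302) and Hoxc9 (adjusted p = 0.0769) were not. The cause was not tested.

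With the replicate block (embryo batch between layers, replicate number otherwise) the counts rose to 6573, 7531, 6197 and 7080 between layers by stage, to 5480 in ectoderm and 7987 in mesoderm from E9.5 to E12.5, to 3588 for the interaction, to 2371, 434 and 565 for the ectoderm steps, to 4297, 746 and 805 for the mesoderm steps, to 411 genes for exon use and to 6 Hoxc genes at E9.5. With only the groups compared they were 1632 between layers at E11.5, 2711 for mesoderm, 806 for its first step and 0 for the last 2 steps of both layers, where fewer samples set the spread. Under a fold threshold of 2 the average layer difference was 3654 genes. With every gene of at least 1 count the 3 ectoderm steps gave 1209, 500 and 639 genes and the last 2 mesoderm steps 545 and 553. DESeq2 gave 1157, 222 and 418 for the ectoderm steps, 2153, 399 and 404 for the mesoderm steps and 1967 for the interaction. Scaling to library totals gave 2 genes for the second ectoderm step. On log2(FPKM + 1) limma gave 94 and 129 for the last 2 ectoderm steps and 94 for the last mesoderm step, with a pseudocount of 0.1 it gave 7 for the second ectoderm step, and without a filter 129 and 169 in ectoderm, 95 and 214 in mesoderm and 2 Hoxc genes at E9.5. Exon use gave 59 genes with a bin mean of at least 50 counts and 297 with voom. Gene lists called with an estimated correlation were 4, 4, 6 and 5 by stage, 0 for the average, 1 in ectoderm, 2 in mesoderm and 1 for the interaction, and fry called 20 for the average. The cause was not tested.

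Without 1 library at a time, where the lone library left in a group is assumed to vary like the other groups, the lowest and highest counts were 2084 and 3445 at E9.5, 2692 and 4187 at E10.5, 1803 and 3159 at E11.5, 2927 and 4111 at E12.5, 6432 and 7272 for the average, 1110 and 2519 for ectoderm, 2773 and 4622 for mesoderm, and 649 and 1300 for the interaction. For the steps they were 145 and 694, 0 and 153, and 0 and 252 in ectoderm, and 614 and 1475, 0 and 115, and 0 and 131 in mesoderm. For exon use they were 170 and 238 genes, and for Hoxc genes over time in ectoderm 7 and 8.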
